A study of Mus musculus with 12 samples.

How the data were processed

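Total RNA from the hippocampal CA1 subfield of mice was measured on 12 Affymetrix expression arrays, with 1 biotin-labelled target per array. The samples formed a layout of genotype (wild-type or SUMO-KD) by surgery (sham or 10 minutes of transient forebrain ischemia followed by 3 hours of reperfusion), with 3 samples per group, and each sample pooled tissue of 2 mouse brains, per the labels' protocols. SUMO-KD denotes mice with a knockdown of the small ubiquitin-like modifier (SUMO), a protein that is attached to other proteins. RNA was extracted with Trizol and amplified with a MessageAmp Premier kit, per the labels' protocols.

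The deposited table held 1 linear intensity per probe set and array. The submitters' processing notes name Partek 6.6 and RMA, without saying which step each made. The deposited intensity values did not have the form of RMA output, which is on a log2 scale: they ran from below 1 to above 10000, their quartiles differed between arrays, and the mean of each array after removal of 2% of values at each end was 500.2 on all 12 arrays. That form is the one of single-array Affymetrix signals scaled to a common target. The step that made the table is not given in the sources used here. The plan had assumed log2 values, so the unit differed from the plan, and the tests were run on log2(intensity + 32). The offset of 32 was chosen after seeing the data, from the spread within groups; no offset and offsets of 16 and 64 were run as added alternatives. A fold change is on the log2(intensity + 32) scale and understates the change of dim genes. No detection call was used.

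The table held 22690 probe sets. Of these, 20393 had 1 gene symbol in the platform annotation, 691 had several, and 1606 had no listed gene, among them 64 control probe sets. Entrez identifiers of 20364 single-symbol probe sets were found in the reference gene table, and 0 symbols needed an update. One probe set per gene was used, the one with the highest mean over the 12 arrays, which gave 12394 genes; 4958 genes had more than 1 probe set. Probe sets that list several genes named no gene.

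Group means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values of limma's moderated test over all genes, two-sided, and a gene was called at an adjusted p under 0.05. The comparisons were ischemia against sham in each genotype, SUMO-KD against wild-type within each surgery, the difference of the ischemia responses between genotypes (the interaction), and the mean ischemia response over both genotypes. The size of the SUMO-KD response relative to the wild-type response was the ratio of the mean log2 changes, each signed by the direction of the mean response, over genes called for the mean response. Its difference was tested by exact permutation of the genotype labels within each surgery, two-sided, over 400 assignments. No run date or batch is given in the labels, and the number of arrays limits the precision. Samples are described as biological replicates in the labels, with no statement of litter or surgery day.

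The comparisons, tests, the rule for named genes and 38 gene lists (23 pathways and 15 cell types or regions, from textbook knowledge) were fixed before the data were examined. The rule named the Sumo genes, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and up to 3 called members of each list for ischemia in wild-type. For ischemia, genes were chosen in wild-type and their values are given in both genotypes, so wild-type values are favoured by the choice. For the interaction, where fewer than 5 genes passed, the 5 with the smallest p are given as values. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists within a comparison, again with an estimated correlation, and with fry. Members were also counted with p-values adjusted over the list alone.

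The alternatives chosen beforehand were every probe set by itself, the mean of a gene's probe sets, removal of probe sets marked as shared between transcripts, filters on dim genes, a repeated quantile normalization, centring on the median, the replicate number as a block, fits on the compared groups alone, eBayes with trend and robust settings, array weights, a further 2-fold threshold, and omission of each array in turn. Where an omission left 2 arrays in a group, the pooled spread of the fit was used. The dim filter was applied to the log2 of the deposited intensity, at a mean of at least 5.

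The procedure was tested on simulated data with 200 changed genes among 12394, drawn with each gene's mean over all arrays and its real spread within groups. The noise was drawn independently for each gene and array, without correlation between genes or deviations of whole arrays. The shares below therefore hold for that setting and may not carry over to the real arrays. Of genes changed by 1 on the log2 scale, 88.5% were recovered for ischemia in wild-type, 82.5% for ischemia in SUMO-KD, 82.5% and 86.0% for genotype in sham and after ischemia, and 66.5% for the interaction. At a log2 change of 2 the recovery for the interaction was 96.5%. The share of false calls in these runs lay between 3.62% and 8.29%. In a simulation of the response size a ratio of 0.8 was put in and 0.821 was found, with an exact permutation p of 0.07. The genotype labels of sham and ischemia arrays were permuted together, and the simulated genotypes differed only in the ischemia arrays. This p therefore depended largely on chance differences between the sham arrays. The run does not show how large a difference the test can detect.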

Results

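Gene expression was profiled in the hippocampal CA1 subfield of wild-type and SUMO-KD mice 3 hours after 10 minutes of transient forebrain ischemia or after sham surgery. CA1 pyramidal neurons are known to be vulnerable to such ischemia. Each of the 4 groups held 3 samples, each pooled from 2 mice, and 12394 genes were tested. The question set by the design was how ischemia changed expression in each genotype and whether the knockdown altered it. The median intensity of the arrays ranged from 141 to 162, and 22.4% to 28.6% of probe sets lay below an intensity of 32. Control probe sets for 18S ribosomal RNA were lower in 5 of the 6 ischemia arrays than in the sham arrays. The 3′ control ranged from 5087 to 7569 in sham arrays and from 2829 to 4127 in those 5 arrays, while SUMO-KD ischemia replicate 2 had 6316. The 5′ control ranged from 4194 to 6528 in sham arrays and from 1275 to 1660 in those 5 arrays, with 4127 in SUMO-KD ischemia replicate 2. This difference ran with surgery. Its cause was not tested, and neither was its part in the genes called for ischemia. The ratio of 3′ to 5′ signal, a sign of RNA integrity, ranged from 1.42 to 1.74 for Actb and from 0.727 to 0.845 for Gapdh over all arrays.

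Sumo3, which encodes a SUMO protein, was lower in SUMO-KD samples. Its intensity was 2343 ± 113 in wild-type sham, 1560 ± 194 in SUMO-KD sham, 3400 ± 140 in wild-type ischemia and 1908 ± 28.3 in SUMO-KD ischemia samples (mean ± SD, n = 3 pools each). The log2 difference between genotypes was −0.58 in sham (SE 0.10, adjusted p = 0.0096) and −0.82 after ischemia (adjusted p = 0.00151). All 3 SUMO-KD arrays lay below all 3 wild-type arrays in each surgery. Ischemia raised Sumo3 by 0.53 in wild-type (adjusted p = 0.00309), and the change in SUMO-KD was 0.29 (adjusted p = 0.081), with an interaction of −0.24 (adjusted p = 0.866). A second Sumo3 probe set had group means from 1.94 to 4.93, which is background, and the sham difference did not pass when both probe sets were averaged (−0.27, adjusted p = 0.159) or when the sham groups alone entered the fit (adjusted p = 0.0719). Sumo2 was not analysed here, because its 2 probe sets list several genes. Of the 12 measured genes of the SUMO pathway, 3 rose with ischemia in wild-type (3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0521). The 3 rises became 1 without wild-type sham replicate 3, wild-type ischemia replicate 1 or wild-type ischemia replicate 3. In SUMO-KD 0 rose and 1 fell by limma (0 and 1 adjusted over the list alone; camera adjusted p = 0.399).

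In wild-type CA1, Atf3, Ccn1, Egr2, Hspa1a and Fos had the largest rises with ischemia among called genes whose groups did not overlap. Atf3, a stress-induced transcription factor, rose by 4.88 on the log2 scale (SE 0.18, adjusted p = 1.07e-07), from an intensity of 53.8 ± 24.3 to 2432 ± 140 (SD, n = 3). Hspa1a, an inducible HSP70 chaperone, rose by 3.63 (SE 0.17), and Fos, a component of the AP-1 transcription factor, rose by 3.59 (SE 0.24). In all, 2289 genes changed in limma's test, 1188 higher and 1101 lower, while 3883 genes had an unadjusted p under 0.05. Of these calls, 308 were at least 2-fold, 281 of them higher and 27 lower. With each array centred on its median the split was 986 higher and 1426 lower, so the balance of rises and falls depended on scaling.

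The other largest rises in wild-type were of Ccn1 (3.83, SE 0.46), which encodes a matricellular protein, Egr2 (3.68), Gadd45g (3.28), Nptx2 (3.23), Rrad (3.13), Tnfrsf12a (3.10) and Gadd45b (3.06). Each of these 10 genes also rose in SUMO-KD, by 4.32 for Atf3, 4.30 for Ccn1, 3.64 for Egr2, 3.92 for Hspa1a, 4.41 for Fos, 2.58 for Gadd45g, 1.73 for Nptx2, 1.77 for Rrad, 2.85 for Tnfrsf12a and 2.61 for Gadd45b. The largest falls in wild-type were of Slco1a4 (−1.51, SE 0.22), an endothelial transporter, Lct (−1.49), Erbb3 (−1.44), Crebzf (−1.41), Poglut2 (−1.39), Rasl10a (−1.36), P2ry12 (−1.35), a microglial purine receptor, Sirt4 (−1.32), Fzd2 (−1.26) and Alox12b (−1.19). In SUMO-KD the changes were −1.14 for Slco1a4, −1.25 for Lct, −0.90 for Erbb3, −1.29 for Crebzf, −1.02 for Rasl10a, −1.02 for P2ry12, −1.03 for Sirt4 and −1.20 for Fzd2, all of which passed. Poglut2 (−0.45, adjusted p = 0.263) and Alox12b (−0.23, adjusted p = 0.55) did not pass in SUMO-KD, and their interactions did not pass (adjusted p = 0.76 and 0.609). None of these 20 wild-type calls was lost when an array was left out, while 23 of all 96 genes named by the rule for this comparison lost theirs in at least 1 omission. The SUMO-KD call of Erbb3 was lost without SUMO-KD sham replicate 1 (adjusted p = 0.0925), SUMO-KD sham replicate 2 (0.0872), SUMO-KD ischemia replicate 1 (0.067) and SUMO-KD ischemia replicate 3 (0.0791).

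**Figure D1:**
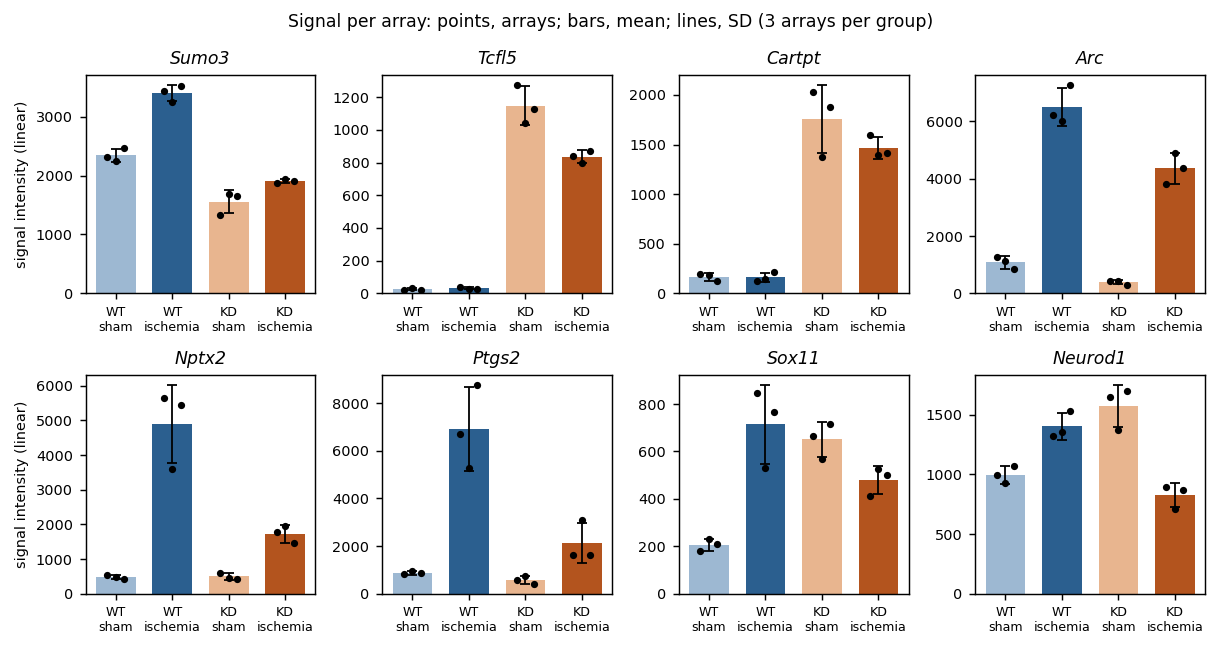
Intensity of Sumo3, Tcfl5, Cartpt, Arc, Nptx2, Ptgs2, Sox11 and Neurod1 on each of the 12 arrays, on linear axes that start at 0, with points for arrays, bars for group means and lines for the SD (n = 3 arrays per group). The mean of Sumo3 was 2343 in wild-type sham and 1560 in SUMO-KD sham samples.

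Among the lists, the immediate early genes moved as a group in both genotypes. In wild-type 28 of 35 rose and 1 fell (30 and 1 adjusted over the list alone), with a median log2 change of 1.41, and in SUMO-KD 29 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 1.54. Camera called this list in both (adjusted p = 4.00e-27 and 1.70e-36; adjusted p = 0.0335 and 0.0126 with an estimated correlation). Of 25 heat shock genes, 15 rose in each genotype, with 1 fall in wild-type (16 rises and 3 falls adjusted over the list alone) and 0 in SUMO-KD (16 and 0). Hspb1 rose by 2.99 in wild-type and by 3.53 in SUMO-KD, and the co-chaperone gene Bag3 rose by 2.37 and 1.70. The heat shock call (adjusted p = 1.03e-09 and 9.53e-15) was lost with an estimated correlation in both genotypes (adjusted p = 0.181 and adjusted p = 0.0789 with an estimated correlation). Of 34 inflammation and NF-kB genes, 19 rose and 1 fell in wild-type (23 and 1 adjusted over the list alone), and 15 rose and 0 fell in SUMO-KD (18 and 0). Cxcl1, a neutrophil-attracting chemokine, rose by 3.00 and 2.73, Nfkbiz by 2.56 and 2.24, and Ptgs2, which encodes an inducible cyclooxygenase, by 2.91 and 1.78. The list was called in both (adjusted p = 6.30e-12 and 1.07e-12), with adjusted p = 0.0571 with an estimated correlation in wild-type and adjusted p = 0.0495 with an estimated correlation in SUMO-KD.

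Genes of the p53 and DNA damage list rose in 10 of 22 cases and fell in 4 in wild-type (11 and 6 adjusted over the list alone), and rose in 8 and fell in 3 in SUMO-KD (10 and 4). Cdkn1a, a cell cycle inhibitor, rose by 2.25 and 1.74. The list was called in both genotypes (adjusted p = 0.000324 and 0.000106), and the call was lost in both (adjusted p = 0.13 and adjusted p = 0.0789 with an estimated correlation). Clock genes rose in 10 of 17 cases with 1 fall in wild-type (10 and 2 adjusted over the list alone) and in 8 with 0 falls in SUMO-KD (9 and 1). Per1 rose by 1.25 and 1.23 and Per2 by 1.21 and 1.24, and this list passed in both (adjusted p = 0.000324 and 0.000175; adjusted p = 0.11 and adjusted p = 0.0789 with an estimated correlation). Glucocorticoid targets rose in 10 of 18 cases and fell in 2 in wild-type (11 and 2 adjusted over the list alone), against 9 and 3 in SUMO-KD (11 and 3). Errfi1, which encodes an inhibitor of EGF receptor signalling, rose by 1.56 and 0.99 (list adjusted p = 4.07e-05 and 0.000717; adjusted p = 0.321 and adjusted p = 0.478 with an estimated correlation). Of 21 hypoxia genes, 8 rose and 1 fell in wild-type (9 and 2 adjusted over the list alone), and 5 rose and 0 fell in SUMO-KD (6 and 1). Bhlhe40 rose by 1.04 and 1.30 and Adm, which encodes the vasodilator adrenomedullin, by 0.97 and 1.28 (list adjusted p = 0.0056 and 0.00718; adjusted p = 0.114 and adjusted p = 0.0789 with an estimated correlation). Some lists share members. Per1 was also in the immediate early and glucocorticoid lists, Cdkn1a in the glucocorticoid list and Bhlhe40 in the clock list, so the results of these lists are not independent. In wild-type the 8 hypoxia rises became 5 without sham replicate 1, 4 without sham replicate 3 and 4 without ischemia replicate 1, and the 4 p53 falls became 1 without sham replicate 1 or ischemia replicate 1 and 2 without sham replicate 2 or ischemia replicate 3. In SUMO-KD the 5 hypoxia rises became 2 without sham replicate 1, ischemia replicate 2 or ischemia replicate 3 and 3 without sham replicate 3. The 3 p53 falls in SUMO-KD became 0 without sham replicate 2 or ischemia replicate 2 and 1 without sham replicate 3 or ischemia replicate 3. The 9 glucocorticoid rises there became 5 without ischemia replicate 2, and the 3 falls 1 without sham replicate 1 or ischemia replicate 3 and 0 without sham replicate 3 or ischemia replicate 2.

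The cholesterol synthesis list moved less, with 5 of 14 members higher and 1 lower in wild-type (6 and 1 adjusted over the list alone) and 2 higher and 1 lower in SUMO-KD (5 and 1). Msmo1 rose by 0.72 and Cyp51 by 0.59 in wild-type, and their SUMO-KD values were 0.37 (adjusted p = 0.0754) and 0.38 (adjusted p = 0.0535). The list passed in wild-type (adjusted p = 0.0169; adjusted p = 0.181 with an estimated correlation) and in SUMO-KD (adjusted p = 0.0387; adjusted p = 0.22 with an estimated correlation). The cholesterol synthesis call in SUMO-KD was lost without SUMO-KD sham replicate 1 (adjusted p = 0.0614), SUMO-KD ischemia replicate 1 (0.0782) and SUMO-KD ischemia replicate 2 (0.0915). Genes of oxidative phosphorylation fell in 9 of 46 cases in wild-type, with 0 rises (11 falls and 0 rises adjusted over the list alone), and 1 fell in SUMO-KD (0 adjusted over the list alone). Sdhd fell by 0.75 in wild-type, Ndufs7 by 0.41 and Ndufb3 by 0.38. The 9 falls became 4 without wild-type sham replicate 1, wild-type ischemia replicate 2, SUMO-KD sham replicate 3 or SUMO-KD ischemia replicate 3, and 3 without wild-type sham replicate 3, wild-type ischemia replicate 1 or wild-type ischemia replicate 3. The oxidative phosphorylation list was lower in wild-type (adjusted p = 4.04e-05; adjusted p = 0.547 with an estimated correlation) and in SUMO-KD (adjusted p = 0.0408; adjusted p = 0.885 with an estimated correlation). In SUMO-KD this call was lost without SUMO-KD sham replicate 1 (0.225), SUMO-KD sham replicate 3 (0.183), SUMO-KD ischemia replicate 2 (0.268) and SUMO-KD ischemia replicate 3 (0.0551).

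The interferon, NRF2, neurotrophic and splicing lists passed at the preset correlation in wild-type and not in SUMO-KD; their interactions had camera adjusted p-values of 1.67e-05, 0.146, 0.0127 and 0.111. The interferon and neurotrophic interaction calls were lost with the other correlation setting (both adjusted p = 0.663 with an estimated correlation). Of 24 interferon response genes, 10 rose and 0 fell in wild-type (12 and 0 adjusted over the list alone), among them the guanylate-binding protein genes Gbp3 (1.92) and Gbp2 (1.45). In SUMO-KD 1 rose and 0 fell (1 and 0 adjusted over the list alone), and the list had adjusted p = 1.60e-05 in wild-type (adjusted p = 0.294 with an estimated correlation) and adjusted p = 0.171 in SUMO-KD. Of 20 NRF2 and oxidative stress genes, 7 rose and 0 fell in wild-type (7 and 0 adjusted over the list alone), and 3 rose and 1 fell in SUMO-KD (3 and 1). Hmox1, which encodes the inducible heme oxygenase, rose by 2.65 and 2.33 (list adjusted p = 0.0159 in wild-type, adjusted p = 0.394 with an estimated correlation, and 0.0643 in SUMO-KD). Of 18 neurotrophic and secreted factors, 5 rose and 0 fell in wild-type (5 and 0 adjusted over the list alone), and 3 rose and 1 fell in SUMO-KD (4 and 1). Hbegf, an EGF receptor ligand gene, rose by 2.22 and 1.60 (list adjusted p = 0.0056 in wild-type, adjusted p = 0.228 with an estimated correlation, and 0.0732 in SUMO-KD). Of 28 splicing factors, 8 rose and 0 fell in wild-type (11 and 1 adjusted over the list alone), and 4 rose and 1 fell in SUMO-KD (5 and 1). Ptbp1 rose by 1.37 and 0.96 and Tra2b by 0.73 and 0.63 (list adjusted p = 0.0056 in wild-type, adjusted p = 0.199 with an estimated correlation, and 0.0508 in SUMO-KD). In wild-type the 10 interferon rises became 5 without sham replicate 1, 4 without ischemia replicate 1 and 6 without ischemia replicate 2, and the 8 splicing rises became 4 without sham replicate 1 and 5 without ischemia replicate 1 or 3. The 4 splicing rises in SUMO-KD became 2 without sham replicate 1, sham replicate 2, ischemia replicate 2 or ischemia replicate 3.

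The ER stress list was called in SUMO-KD, where 8 of 33 members rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00266, and adjusted p = 0.537 with an estimated correlation). In wild-type 6 rose and 4 fell (8 and 6 adjusted over the list alone; adjusted p = 0.407). Chac1 rose by 2.93 and 2.65 and Ppp1r15a, which encodes a phosphatase subunit acting on eIF2α, by 1.86 and 2.06. The remaining pathway lists passed in neither genotype, and their wild-type counts follow. Of 26 apoptosis regulators 5 rose and 3 fell (8 and 4 adjusted over the list alone), including Mcl1 (0.99), and of 15 genes of the glutamate receptor list 0 rose and 1 fell (0 and 1). The fall was of Cacng8 (−0.67), which encodes an auxiliary subunit and not a receptor itself. The GABA-A receptor list was drawn up with GABA-B receptor genes and the scaffold gene Gphn as well. Of its 9 measured genes 0 passed in limma's test, of 25 synaptic vesicle and scaffold genes 1 rose and 3 fell (1 and 3), and of 26 voltage-gated channel genes 1 rose and 1 fell (1 and 0). Of 31 proteasome genes 0 rose and 2 fell (0 and 1), of 41 cytosolic ribosomal protein genes 2 rose and 0 fell (2 and 0), and of 17 glycolysis genes 1 rose and 1 fell (0 and 0). In wild-type the 4 ER stress falls became 1 without sham replicate 1 or ischemia replicate 1 and 2 without sham replicate 2, ischemia replicate 2 or ischemia replicate 3. The 5 apoptosis rises became 2 without sham replicate 1, sham replicate 3 or ischemia replicate 3 and 3 without ischemia replicate 1, and the 3 apoptosis falls 0 without sham replicate 1 or ischemia replicate 1 and 1 without sham replicate 2, sham replicate 3 or ischemia replicate 3. The 3 synaptic falls became 1 without sham replicate 1, sham replicate 3 or ischemia replicate 3. Over all lists and the 4 comparisons of ischemia and genotype, counts of up to 2 members ranged from 0 to 3 with an array left out.

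**Figure D2:**
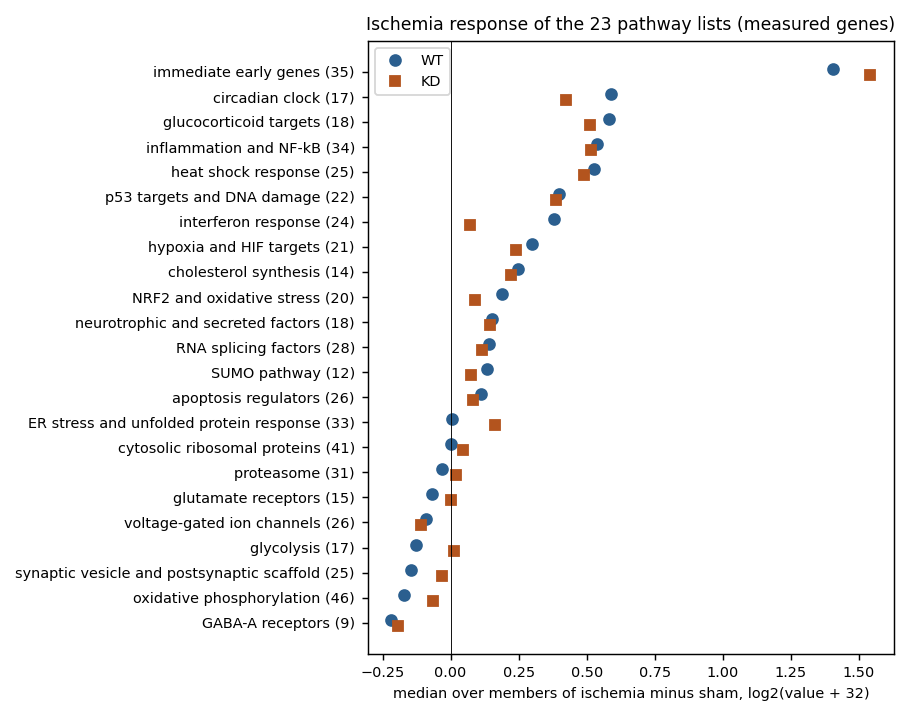
Median log2 change after ischemia against sham of the 23 pathway lists, with the number of measured genes in brackets, in wild-type and SUMO-KD mice, with circles for wild-type and squares for SUMO-KD. The immediate early genes had the largest medians of the lists shown, 1.41 in wild-type and 1.54 in SUMO-KD.

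Single markers of cell types passed in limma's test, while 0 of the 15 cell type lists passed by camera in wild-type and 2 in SUMO-KD. Of all 12394 genes, 2289 were called in wild-type and 1327 in SUMO-KD. A few called markers in a list are therefore not by themselves a change of that cell type. Microglial markers fell in 4 of 17 cases in each genotype, with 1 rise in wild-type (1 and 4 adjusted over the list alone) and 0 in SUMO-KD (0 and 5). Tmem119 fell by 0.90 in wild-type and by 0.95 in SUMO-KD and Gpr34 by 0.83 and 1.17. The microglia list was called in SUMO-KD (adjusted p = 0.0287; adjusted p = 0.376 with an estimated correlation) and not in wild-type (0.434). The microglia call was lost without SUMO-KD sham replicate 2 (adjusted p = 0.0719) or SUMO-KD ischemia replicate 2 (0.0615). Endothelial markers went both ways, with 3 of 16 higher and 5 lower in wild-type (3 and 5 adjusted over the list alone) and 2 higher and 3 lower in SUMO-KD (2 and 3). Cdh5, which encodes VE-cadherin, rose by 0.91 and 0.84, and Abcb1a, an efflux transporter gene of the blood-brain barrier, fell by 0.83 and 0.95. Of 9 dentate granule markers, 1 rose and 2 fell in wild-type (2 and 3 adjusted over the list alone) and 0 rose and 3 fell in SUMO-KD (0 and 7). The dentate list was lower in SUMO-KD (adjusted p = 0.000278; adjusted p = 0.223 with an estimated correlation). Its 3 falls became 5 without wild-type sham replicate 2, and the 5 endothelial falls in wild-type became 3 without wild-type sham replicate 1.

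Of 18 astrocyte markers, 3 rose and 0 fell in wild-type (4 and 1 adjusted over the list alone), including Vim (1.22) and Sox9 (1.05). Of 15 oligodendrocyte markers 0 rose and 3 fell (0 and 3), including Ugt8a (−0.97), and of 6 precursor markers 0 rose and 2 fell (0 and 3), including Pdgfra (−1.06). Of 8 CA1 pyramidal markers 0 rose and 2 fell in wild-type (0 and 6 adjusted over the list alone; camera adjusted p = 0.0521), and 0 passed in SUMO-KD in limma's test. Wild-type counts of the remaining lists were 0 of 9 CA3 markers, 3 falls among 15 interneuron markers, 1 rise among 13 mural markers and 0 of 14 choroid plexus and ependymal markers. They were 1 rise among 12 leptomeningeal markers, 1 fall among 6 red blood cell markers, 1 fall among 13 neutrophil and monocyte markers and 1 rise among 11 thalamus and striatum markers. Adjusted over the list alone these counts were equal, except for 2 falls of red blood cell markers. None of these lists was called in either genotype. By fry, another list test, all 13 lists that camera called in wild-type also passed, and 11 of the 12 called in SUMO-KD did, the exception being oxidative phosphorylation (fry adjusted p = 0.265). Fry asks whether members changed at all, while camera asks whether they changed more than other genes. With 2289 genes called in wild-type and 1327 in SUMO-KD, passing by fry does not show that a list changed more than other genes. The 2 CA1 falls became 0 without wild-type sham replicate 1 or wild-type ischemia replicate 3 and 1 without wild-type sham replicate 2, wild-type sham replicate 3, wild-type ischemia replicate 1, SUMO-KD sham replicate 3 or SUMO-KD ischemia replicate 3. The 3 interneuron falls became 0 without wild-type sham replicate 1, wild-type sham replicate 2, wild-type ischemia replicate 2 or wild-type ischemia replicate 3, and 1 without wild-type sham replicate 3, SUMO-KD sham replicate 3 or SUMO-KD ischemia replicate 3. Median, mean and test differed in sign in wild-type for the astrocyte list (median −0.03, mean 0.11, test upward) and the mural list (median −0.05, mean 0.01, test downward), and the ribosomal list had a median of 0. In SUMO-KD they differed for the glutamate receptor, interneuron, oligodendrocyte and leptomeningeal lists, with medians from −0.03 to 0.08.

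In SUMO-KD CA1, ischemia changed 1327 genes, 754 higher and 573 lower, of which 198 were at least 2-fold (176 higher, 22 lower), and 2991 had an unadjusted p under 0.05. With each array centred on its median the split was 650 higher and 645 lower. The rises of Fos, Atf3, Ccn1 and Hspa1a given before were the largest of the genes named in wild-type. Of genes called in both genotypes, 616 were higher in both, against 72.3 for independent lists, and 409 were lower in both, against 50.9, while 3 went opposite ways. The 2 comparisons share no arrays in their means, but they share 1 estimate of the spread, which favours genes with a small spread in both lists. Across all 12394 genes the log2 changes of the 2 genotypes had a Pearson r of 0.779 and a Spearman rho of 0.638, where genes are not independent replicates. The SUMO-KD count fell to 845 without SUMO-KD sham replicate 1, 879 without SUMO-KD sham replicate 2, 762 without SUMO-KD ischemia replicate 2 and 786 without SUMO-KD ischemia replicate 3.

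**Figure D3:**
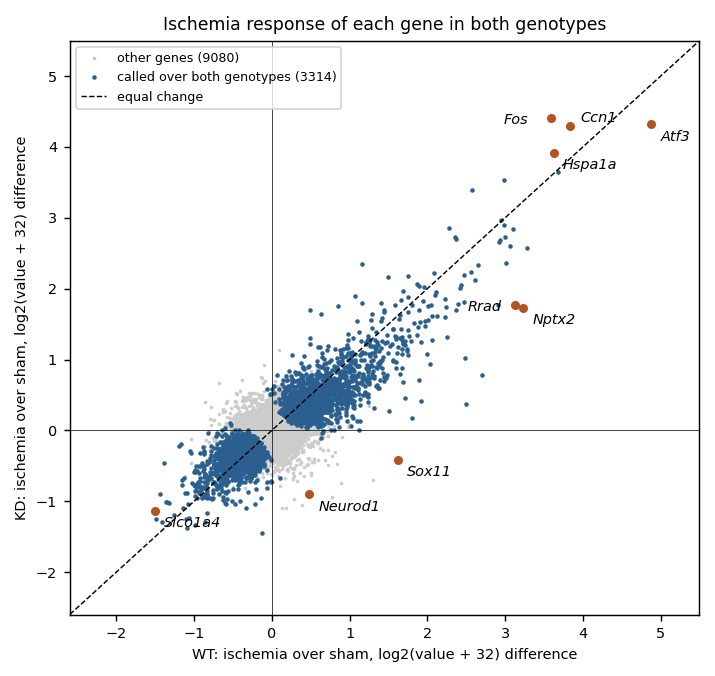
Log2 change after ischemia in wild-type (horizontal axis) against SUMO-KD (vertical axis), 1 point per gene. The 3314 genes called for the mean response over both genotypes are in blue, other genes in grey, 9 named genes in orange, and the dashed line marks an equal change. Across all 12394 genes the Pearson r was 0.779.

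Over both genotypes, 3314 genes changed with ischemia, 1582 higher and 1732 lower, and 4651 had an unadjusted p under 0.05; with each array centred on its median the split of 3627 calls was 1348 higher and 2279 lower. Of these calls 229 were at least 2-fold, 214 higher and 15 lower. Over the 3314 genes the mean signed log2 change was 0.56 in wild-type and 0.46 in SUMO-KD, a ratio of 0.832, and the difference of −0.09 did not pass (exact permutation p = 0.17, 400 assignments, two-sided). The rises had a ratio of 0.828 (exact p = 0.12) and the falls 0.838 (exact p = 0.265), and 67.0% of the genes, 2222 of 3314, had a smaller change in SUMO-KD. The score of each array was 0.57, 0.50 and 0.60 in wild-type ischemia samples and 0.39, 0.52 and 0.45 in SUMO-KD ischemia samples, and SUMO-KD sham samples had −0.01 ± 0.02 (SD, n = 3).

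**Figure D4:**
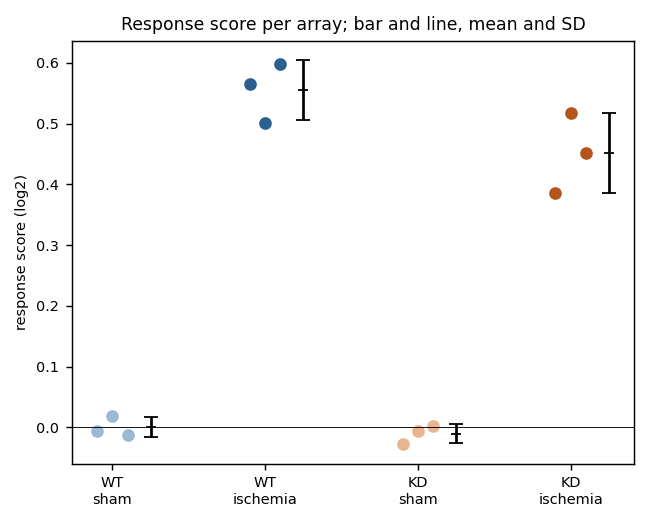
Ischemia response score per array, the mean log2 value over 3314 genes signed by the direction of their mean response and set to 0 at the wild-type sham mean, with points for arrays and, beside them, the group mean and SD. The 3 SUMO-KD ischemia arrays had 0.39, 0.52 and 0.45 and the 3 wild-type ischemia arrays 0.57, 0.50 and 0.60.

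Between genotypes in sham mice, the largest differences were of genes higher in SUMO-KD. Tcfl5, which encodes a basic helix-loop-helix transcription factor, was higher by 4.38 on the log2 scale (SE 0.11, adjusted p = 2.39e-09, n = 3 pools per group), Cartpt, a neuropeptide gene, by 3.15 (SE 0.20) and Grp, which encodes gastrin-releasing peptide, by 2.80 (SE 0.13). Pcdhb22, a clustered protocadherin gene, was higher by 2.54, Tmem30b by 2.51, Ogn by 2.44, Baiap3 by 2.36, Kdf1 by 2.27, Lox, which encodes lysyl oxidase, by 2.26 and Cdhr1 by 2.24. The largest differences in the other direction were of Ighm (−1.77), Arc (−1.40), an activity-regulated gene of neurons, the chemokine gene Cxcl12 (−1.39), Zfpm1 (−1.36), Nr4a1 (−1.22), Nr4a2 (−1.08), Wnt2 (−1.05), Depdc7 (−1.04), Cd34 (−1.04) and Grem1 (−1.02). In limma's test 260 genes differed, 186 higher and 74 lower in SUMO-KD, of which 70 were at least 2-fold (59 and 11), and 1758 had an unadjusted p under 0.05.

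Among the lists, 5 of 35 immediate early genes were lower and 0 higher in SUMO-KD sham samples (12 and 2 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 2.25e-05; adjusted p = 0.539 with an estimated correlation). The 5 included Arc, Nr4a1 and Nr4a2. They became 2 without wild-type sham replicate 1 or SUMO-KD sham replicate 3 and 3 without SUMO-KD sham replicate 1. Of 8 CA1 pyramidal markers 2 were lower and 0 higher (6 and 0 adjusted over the list alone), with a median of −0.77 (adjusted p = 2.25e-05; adjusted p = 0.539 with an estimated correlation). The 2 became 0 without wild-type sham replicate 1 or SUMO-KD sham replicate 3 and 1 without wild-type sham replicate 3, wild-type ischemia replicate 2 or SUMO-KD sham replicate 1. The CA1 list mean on each array was 9.83, 9.58 and 9.50 in wild-type sham and 8.94, 9.24 and 8.83 in SUMO-KD sham samples. The heat shock list had 1 of 25 lower and 0 higher (3 and 0 adjusted over the list alone), with adjusted p = 0.00553 and adjusted p = 0.743 with an estimated correlation. The ER stress list had 1 of 33 lower and 0 higher (1 and 0 adjusted over the list alone), also with adjusted p = 0.00553 and adjusted p = 0.743 with an estimated correlation. The oligodendrocyte list had 0 of 15 called by limma and a median of −0.24 (adjusted p = 0.00919; adjusted p = 0.743 with an estimated correlation), and the cholesterol synthesis list had 0 of 14 called and a median of 0.18 (adjusted p = 0.0105; adjusted p = 0.539 with an estimated correlation). None of these 6 lists passed by fry (adjusted p from 0.0955 for cholesterol synthesis to 0.281), where the immediate early genes had 0.136 and the CA1 markers 0.118. The remaining 32 lists did not pass, and median, mean and test differed in sign for 8 of them, the widest being the interneuron list (median −0.26, mean 0.06, test downward). Without wild-type sham replicate 1 the heat shock and ER stress lists had adjusted p = 0.18, and the heat shock call was also lost without SUMO-KD sham replicate 3 (0.0607). The oligodendrocyte call was lost without wild-type sham replicate 1 (0.0673), wild-type sham replicate 3 (0.0826) or SUMO-KD sham replicate 1 (0.124).

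The count of 260 moved to 112 without wild-type sham replicate 1, 147 without wild-type sham replicate 2, 131 without SUMO-KD sham replicate 1 and 112 without SUMO-KD sham replicate 3, and to 130 with the sham groups alone in the fit. The call of Grem1 was lost without wild-type sham replicate 1 (adjusted p = 0.0624). Depdc7 was lost without wild-type sham replicate 1 (0.0623), SUMO-KD sham replicate 1 (0.0556) or SUMO-KD sham replicate 3 (0.055). Nr4a1 was lost without wild-type sham replicates 1 (0.0657) and 2 (0.0553) and SUMO-KD sham replicates 1 (0.0554) and 3 (0.06), and Nr4a2 without the same 4 arrays in turn (0.0619, 0.0742, 0.079 and 0.0682). Cd34 kept its call in only 3 of the 12 omissions, those of wild-type ischemia replicates 2 and 3 and SUMO-KD sham replicate 2, with an adjusted p up to 0.178 in the other 9.

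After ischemia, Tcfl5 was again the gene with the largest difference, higher in SUMO-KD by 3.76 (SE 0.11, adjusted p = 1.34e-08, n = 3 pools per group), followed by Cartpt (2.96), Tmem30b (2.56), Grp (2.35), Col6a1 (2.29), which encodes a collagen chain, Lox (2.13), Kdf1 (1.78), Amn (1.71), Prph (1.68) and Ltbp2 (1.49). The genes with the largest differences in the other direction were mostly genes that rose with ischemia in wild-type. They were chosen on the difference after ischemia, and the wild-type rise uses the same wild-type ischemia arrays. The choice therefore favours larger rises in wild-type than in SUMO-KD. Xirp1 differed by −2.08 between genotypes and rose by 2.50 in wild-type, with 0.37 in SUMO-KD (adjusted p = 0.504). Inhba, which encodes a subunit of activin A, differed by −2.07 and rose by 1.81 in wild-type, with 0.17 in SUMO-KD (adjusted p = 0.723). Acan, a proteoglycan gene, was lower in SUMO-KD (adjusted p = 0.00885) and rose by 2.70 in wild-type, with 0.79 in SUMO-KD (adjusted p = 0.129). Ptgs2 differed by −1.73, Pim1 by −1.66, Cavin1 by −1.48, Nptx2 by −1.47 and Rgs2, a regulator of G protein signalling, by −1.25. Ighm (−1.41) and Cxcl12 (−1.27) were lower in both surgeries. The interactions of Xirp1 and Inhba had an adjusted p of 0.229, and those of Acan, Ptgs2, Pim1, Cavin1, Nptx2 and Rgs2 had 0.425, 0.718, 0.145, 0.711, 0.175 and 0.145, so no difference of the ischemia response passed for these 8 genes.

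In limma's test 193 genes differed between genotypes after ischemia, 124 higher and 69 lower in SUMO-KD, of which 49 were at least 2-fold (36 and 13), and 1915 had an unadjusted p under 0.05. Of 24 interferon response genes 1 was lower (4 adjusted over the list alone) and 0 higher, with a median of −0.28 (camera adjusted p = 5.14e-05; adjusted p = 0.851 with an estimated correlation). Of 46 oxidative phosphorylation genes 0 passed in limma's test, with a median of 0.12 (adjusted p = 0.000206; adjusted p = 0.851 with an estimated correlation). Of 35 immediate early genes 3 were lower and 0 higher (9 and 1 adjusted over the list alone), with adjusted p = 0.000559 (adjusted p = 0.851 with an estimated correlation) and 0.112 without SUMO-KD ischemia replicate 2. The 3 became 1 without SUMO-KD ischemia replicate 1 or 3 and 2 without SUMO-KD ischemia replicate 2, and the 1 interferon gene became 0 without wild-type sham replicates 1, 2 or 3, wild-type ischemia replicates 1 or 2 or SUMO-KD ischemia replicates 1 or 3, and 2 without SUMO-KD sham replicate 1 or SUMO-KD ischemia replicate 2. Of 34 inflammation and NF-kB genes 1 was lower (1 adjusted over the list alone), with adjusted p = 0.000651 (adjusted p = 0.851 with an estimated correlation). None of these 4 lists passed by fry (adjusted p from 0.271 to 0.308). The other 34 lists did not pass, and signs of median, mean and test differed for 7 of them, the widest being the neutrophil and monocyte list (median −0.14, mean 0.06, test downward).

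Between sham and ischemia, 69 genes were higher in SUMO-KD in both surgeries, against 1.86 for independent lists, 10 were lower in both, against 0.412, and 1 differed in opposite ways. These comparisons share no arrays in their means, but they share 1 estimate of the spread, which favours genes with a small spread in both lists. Across all genes the genotype differences in the 2 surgeries had a Pearson r of 0.508 and a Spearman rho of 0.41. The count of 193 moved to 84 without wild-type ischemia replicate 1, 94 without SUMO-KD ischemia replicate 1, 60 without SUMO-KD ischemia replicate 3 and 48 with the ischemia groups alone in the fit. Single calls were lost without SUMO-KD ischemia replicate 3 for Ptgs2 (adjusted p = 0.053), Cavin1 (0.0982) and Ltbp2 (0.0796), without SUMO-KD ischemia replicate 1 for Cavin1 (0.0826) and Cxcl12 (0.0531), and without wild-type ischemia replicate 1 for Ltbp2 (0.0549). With the probe sets of a gene averaged, the differences after ischemia did not pass for Prph (0.36), Ighm (−0.25), Cxcl12 (−0.54), Cavin1 (−0.62) and Ptgs2 (−1.38).

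The ischemia response itself differed between genotypes for 2 of 12394 genes, both transcription factor genes of neuronal development, while 768 had an unadjusted p under 0.05. A share of 0.05 of unchanged genes would reach such a p by chance alone. Sox11 rose by 1.62 in wild-type (SE 0.16, n = 3 pools per group) and changed by −0.42 in SUMO-KD (adjusted p = 0.142), an interaction of −2.04 (SE 0.23, adjusted p = 0.0219). Neurod1 rose by 0.48 in wild-type and fell by 0.91 in SUMO-KD, an interaction of −1.39 (SE 0.17, adjusted p = 0.0219). In sham samples both were higher in SUMO-KD, by 1.51 for Sox11 and 0.64 for Neurod1, and after ischemia the difference was −0.53 for Sox11 (adjusted p = 0.154) and −0.75 for Neurod1 (adjusted p = 0.0103). The next genes by p were Rrad (−1.36), Dyrk3 (−1.18) and Camk2d (−1.01), each with adjusted p = 0.145. Both calls held without wild-type ischemia replicate 1 (3 genes called), wild-type ischemia replicate 2 (5) or SUMO-KD sham replicate 2 (3). They were lost without wild-type sham replicate 1 (adjusted p = 0.109 for Neurod1), 2 (0.099) or 3 (0.0611), wild-type ischemia replicate 3 (0.0579), SUMO-KD sham replicate 1 (0.115) or 3 (0.103), and SUMO-KD ischemia replicate 1 (0.0566), 2 (0.0521) or 3 (0.0698). In those 9 omissions 0 genes passed in limma's test, and between 632 and 833 genes had an unadjusted p under 0.05. With no offset 0 genes passed in limma's test, with 711 at an unadjusted p under 0.05.

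By camera at the preset correlation, 8 lists differed in their ischemia response, and 0 did with an estimated correlation or by fry (fry adjusted p = 0.586 for each of the 8). The interferon response list had a median difference of −0.38 (adjusted p = 1.67e-05; adjusted p = 0.663 with an estimated correlation), with 0 of 24 members passing over all genes in limma's test and 2 lower adjusted over the list alone. In the exact permutation of genotype over 400 assignments it had p = 0.1 (adjusted p = 0.633 over 38 lists), and the smallest exact p of a list, 0.035 for glycolysis, had an adjusted p of 0.608. The other 7 lists, ER stress, neurotrophic factors, oxidative phosphorylation, CA1, dentate, astrocytes and oligodendrocytes, had camera adjusted p-values between 0.00667 and 0.0184 and each lost its call without at least 2 of the arrays, each named below with its value.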

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

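Of the tests in this part, the splits of the arrays were set before their results were seen; the test on the immediate early and heat shock genes, whose bound was also changed after its result, and the test on the share of CA1 tissue were chosen only after the result was seen.

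The ischemia response of 2 genes differed between genotypes in a test of the difference itself. The response of Sox11 was lower in SUMO-KD by 2.04 (SUMO-KD minus wild-type −2.04, SE 0.23, adjusted p = 0.0219), and that of Neurod1 by 1.39 (−1.39, SE 0.17, adjusted p = 0.0219). Both genes are known for their part in the differentiation of neurons, Neurod1 in dentate granule cells. The dentate marker list had the same signs, with a mean of 0.19 in sham and −0.13 after ischemia (SUMO-KD minus wild-type, camera adjusted p = 0.23 and 0.436), neither of which passed, so a different share of dentate tissue between the groups stays open for these genes. Over 100 regroupings of genotype within surgery, 2, the real one included, gave as many as 2 genes, with 2 as the highest of the others. The share was under 0.05, but such regroupings also mix genotype differences common to both surgeries into the spread. That makes interaction calls rarer in them, so the share is no support for a difference of the response itself. Both calls were lost without wild-type sham replicate 1 (adjusted p = 0.109 for Neurod1), 2 (0.099) or 3 (0.0611), wild-type ischemia replicate 3 (0.0579), SUMO-KD sham replicate 1 (0.115) or 3 (0.103), and SUMO-KD ischemia replicate 1 (0.0566), 2 (0.0521) or 3 (0.0698).

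The responses of 8 gene lists differed between genotypes by camera at the preset correlation, and none did with an estimated correlation, where the lowest adjusted p was 0.663, or by fry (adjusted p = 0.586 for each of the 8). Median differences (SUMO-KD minus wild-type) were 0.111 for ER stress (adjusted p = 0.0127; adjusted p = 0.684 with an estimated correlation), −0.383 for the interferon response (1.67e-05; adjusted p = 0.663 with an estimated correlation) and −0.074 for neurotrophic and secreted factors (0.0127; adjusted p = 0.663 with an estimated correlation). They were 0.099 for oxidative phosphorylation (0.00667; adjusted p = 0.7 with an estimated correlation), 0.357 for CA1 pyramidal markers (0.011; adjusted p = 0.663 with an estimated correlation) and −0.41 for dentate granule markers (0.0127; adjusted p = 0.663 with an estimated correlation). Astrocyte markers had −0.096 (0.0184; adjusted p = 0.663 with an estimated correlation) and oligodendrocyte markers 0.211 (0.00741; adjusted p = 0.663 with an estimated correlation). By limma 0 members of any of the 8 passed over all genes. Adjusted over the list alone, 2 interferon genes, 4 neurotrophic factors, 1 dentate and 1 astrocyte marker were lower and 1 CA1 marker was higher. The sign of median, mean and test differed for the glutamate receptor, GABA-A receptor, ribosomal and interneuron lists, which did not pass.

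The interferon call at the preset correlation held without each array in turn. It was lost with an estimated correlation (adjusted p = 0.663) and by fry (adjusted p = 0.586), and in the exact permutation of genotype the list had p = 0.1 (adjusted p = 0.633). The ER stress call was lost without wild-type sham replicate 1 (adjusted p = 0.228) or SUMO-KD ischemia replicate 2 (0.199), and the oligodendrocyte call without wild-type ischemia replicate 3 (0.103) or SUMO-KD sham replicate 1 (0.0996). The call of neurotrophic factors was lost without wild-type sham replicate 2 (0.0869), wild-type ischemia replicate 3 (0.103) or SUMO-KD ischemia replicate 2 (0.0692) or 3 (0.054). Oxidative phosphorylation was lost without wild-type sham replicate 1 (0.0504) or 3 (0.0636), wild-type ischemia replicate 3 (0.0898), SUMO-KD sham replicate 2 (0.178) or SUMO-KD ischemia replicate 1 (0.0924). The CA1 list was lost without wild-type sham replicate 1 (0.0823), wild-type ischemia replicate 3 (0.221), SUMO-KD sham replicate 3 (0.0659) or SUMO-KD ischemia replicate 1 (0.0924). Dentate markers were lost without wild-type sham replicate 2 (0.0869), SUMO-KD sham replicate 1 (0.0996) or SUMO-KD ischemia replicate 2 (0.112). Astrocyte markers were lost without wild-type sham replicate 2 (0.0869), wild-type ischemia replicate 1 (0.138), SUMO-KD sham replicate 3 (0.0819) or SUMO-KD ischemia replicate 2 (0.198).

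Fewer genes were called after ischemia in SUMO-KD (1327) than in wild-type (2289), a gap of 962. Over 100 regroupings of genotype within surgery, 11 gave a gap as large, with 1288 as the highest of the others, so chance was not excluded. A milder ischemia or less responding tissue in the SUMO-KD samples would make the early genes smaller too, but over 60 immediate early and heat shock genes the ratio of the SUMO-KD to the wild-type response was 1.08 (1.05 to 1.14 with each array left out), against 0.832 over all called genes. It stays open, because those genes had lower means in SUMO-KD by 0.27 in sham and by 0.16 after ischemia, so the ratio also depends on their sham level. An effect of the knockdown on the response is likewise open and was not separated from these.

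The mean over the 8 CA1 pyramidal markers was lower in SUMO-KD sham samples by 0.63 (SE 0.16), with 2 of the 8 passing by themselves. The list call was lost with an estimated correlation (adjusted p = 0.539) and by fry. The splits of the 6 arrays were too few for a share under 0.05: 1 of 10 gave a difference as large, the real one, at 0.634, and the highest other was 0.461. A lower share of CA1 tissue in the SUMO-KD sham dissections would raise markers of other types alike only if all of them filled its place. Of 14 other lists 2 were lower by more than 2 SE, endothelial (−0.14) and mural cells (−0.14), and 1 was higher, astrocytes (0.08). Tissue of 1 neighbouring region would raise the markers of that region alone. The dentate list was higher by 0.19 (SE 0.12) and the CA3 list had −0.20 (SE 0.11), neither beyond 2 SE. The test therefore decides nothing, also since some of 14 lists pass 2 SE by chance, and a lower CA1 share stays open. A lower expression of some of these markers with the knockdown stays open.

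The other counts were set against splits of the same 6 arrays, which at 10 splits are too few for a share under 0.05. As many genes were called in 1 of 10 splits, the real one, for ischemia in wild-type (2289, highest other 0), ischemia in SUMO-KD (1327, highest other 1), genotype in sham (260, highest other 1) and genotype after ischemia (193, highest other 0). For ischemia over both genotypes, 1 of 100 regroupings of surgery within genotype, the real one, gave as many as 3314 genes, with 851 as the highest other. That share is under 0.05, so a chance division of the arrays was unlikely to give this count, though 100 drawn regroupings do not exclude it.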

How the results depend on the processing

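The settings with no offset and offsets of 16 and 64 were chosen only after the data were seen; the others were set before. Of the alternative values of named genes, 5758 kept direction and side of the threshold, 340 lost their call, 46 gained one and 8 reversed; of those of gene lists 997 kept both, 121 lost the call and 0 reversed. Unless a reason is given, the cause was not tested.

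With every probe set tested by itself (22690 instead of 12394 features), 3479 were called for ischemia in wild-type and 5120 over both genotypes. With only the groups compared, which leaves fewer arrays for the spread, 130 genes differed between genotypes in sham and 48 after ischemia; array weights gave 457 and 331, and no offset 152 and 97, with 0 for the interaction by limma (711 at an unadjusted p under 0.05). A further 2-fold threshold, which can only lower counts, left 308, 198, 70, 49 and 229 genes for ischemia in wild-type, in SUMO-KD, genotype in sham, after ischemia and ischemia over both genotypes.

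The labels do not say that same-numbered samples share an animal or a day. Of 18 same-numbered pairs 5 had a correlation over 0.1 (range −0.166 to 0.276, median 0.0585), and in 10 of 18 the own number gave the best match, where chance gives 1 in 3, so a weak structure by number is not excluded. With the replicate block the interaction had 1 gene, Neurod1 (adjusted p = 0.0131), the call of Sox11 was lost (adjusted p = 0.0615), and the other counts were 2294, 1299, 258, 180 and 3376.

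The response ratio was 0.6988 (exact permutation p = 0.005, the smallest the 400 assignments can give) over genes called in wild-type and 1.01 (exact p = 0.9) over genes called in SUMO-KD, since choosing genes in 1 genotype favours its response. With each array left out in turn, counts ranged from 1546 to 2307 for ischemia in wild-type, 762 to 1405 in SUMO-KD, 112 to 271 for genotype in sham, 60 to 210 after ischemia, 0 to 5 for the interaction and 2684 to 3321 over both genotypes, and the ratio from 0.769 to 0.914.

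Reversed values were all of changes in SUMO-KD except 1 of Sumo3. Without probe sets shared between transcripts, Sumo3 falls to its background probe set (−0.0282 for ischemia in SUMO-KD, 0.04875 for genotype in sham). Psmb5 had 0.0006383 after repeated quantile normalization. With arrays left out, Pou3f1 ranged from −0.4046 to 0.07132, Wfs1 from −0.1451 to 0.05472 and Pvalb from −0.0885 to 0.08547. Dim genes are limited by background: 22.4% to 28.6% of probe sets per array lay below an intensity of 32.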

Other observations

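The tests in this part were all chosen only after the result was seen, and the bound for the test on neighbouring genes was changed after its result.

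The 79 genes that differed between genotypes in the same direction in both surgeries had a median absolute log2 difference of 1.03 in sham and 0.97 after ischemia. They were picked out after their values were seen. Single genes among those higher in SUMO-KD were Cartpt (3.15 in sham, 2.96 after ischemia), Grp (2.80, 2.35), Pcsk1 (1.60, 0.75), which encodes a prohormone convertase, Smc5 (1.30, 0.98), Thy1 (0.88, 0.87), which encodes a neuronal surface protein, Gap43 (0.84, 1.02), Wt1 (1.84, 1.22) and Mkrn3 (2.06, 1.30). Enrichment of gene functions among the 79 was not tested. Besides Sumo3, genes lower in both included the serum response factor gene Srf (−0.54, −0.44), Cebpb (−0.50, −0.64), Tgfb2 (−0.91, −0.67) and the channel gene Trpc6 (−0.75, −1.16).

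Mice that carry a transgene may also differ from wild-type mice in a stretch of genome from another strain around the transgene or a locus. Among the 79 genes, 9 pairs lay within 10 neighbouring array genes, against a median of 5 and a 95th percentile of 9 in 10000 random gene sets (share 0.0581), so this stays open. The neighbours were Pcdhb20, Pcdhb21 and Pcdhb22, Col6a1 and Sumo3, Hrh3 and Tcfl5, Prph and Aqp5, Rian and Amn, Plxdc1 and Stac2, and Nmb and Pde8a. A sequence variant under one probe set could mimic a difference, but 85.7% of the other probe sets of these genes, 30 of 35 in 24 genes, went the same way in both surgeries. Of these 35 probe sets 8 passed in both surgeries, and 55 genes with no other probe set stay open. More cells of a listed other type or region in the SUMO-KD dissections would raise most markers of that type by 0.5 only if many such cells were added. The highest share of members higher by 0.5 in both surgeries was 22.2%, 2 of 9 dentate markers. A smaller admixture could stay below that bound, and regions without a list were not covered, so a difference of tissue stays open. An effect of the knockdown itself stays open as well.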
